A study of Rattus norvegicus with 8 samples.

How the data were processed

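Messenger RNA was sequenced in bulk from H9c2 cells, a line of myoblasts derived from rat heart. The 8 libraries formed 2 groups of 4, cells given OxPAPC at 100 µg/ml for 6 h and cells given vehicle. OxPAPC is a mixture of oxidation products of palmitoyl-arachidonoyl-phosphatidylcholine, a phospholipid of membranes and lipoproteins. Per the labels' protocols, cells of passage 6 were plated at 75 k per well, and 250 ng of total RNA per sample went to a sequencing company. All 8 libraries shared 1 batch date, so no batch could be compared with another. The libraries carry the numbers of their titles, 1, 8, 15 and 22 for vehicle and 2, 9, 16 and 23 for OxPAPC. The labels do not say that the samples came from separate cultures, so p-values measure the spread between these samples, part of which may be technical.

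The authors deposited a table of read counts per gene, whole numbers that were not normalized, and a table of FPKM values for the same genes and libraries. Per the submitters' processing notes, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 were used; the notes as given here state no role or order for them. Per the labels' protocols the libraries were both directional and non-directional, so whether strand was used in counting is not known, and reads from genes that overlap on opposite strands may not have been told apart. The genome build is not given in the sources used here. Coordinates are those of the deposited count table, and its sequence names were turned into chromosome numbers through the gene identifiers of a RefSeq gene table of the assembly GRCr8, which served for names only and held 91.9% of the 40994 gene identifiers. In each deposited file 1 line had been emptied for this work, and every other line named a gene. The deposited FPKM values equalled the count divided by gene length in kb and by the library total in M counts, multiplied by 1 factor per library between 0.987 and 1.02, so they hold no information beyond the counts except that scaling.

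Total counts were 15.4 to 21.7 M per library. The files do not record molecular identifiers, so counting intervals and floors cover counting error only; the floor for a gene at 0 was 3 counts over a group. Replicates were compared by a chi-square test over genes with at least 20 counts in a pair. Chi-square per degree of freedom was 2.23 to 9.50 for the 12 pairs of libraries within a group and 23.1 to 35.0 for the 16 pairs across groups, so no library repeated another within sampling noise and each counted as 1 replicate.

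The counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum of 10 counts, at the median library size, in at least 4 libraries and 15 counts in total, which left 13206 genes. Libraries were scaled by TMM, with factors of 0.976 to 1.03, and tested by the quasi-likelihood F test with robust estimation. P-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was taken as changed at an adjusted p under 0.05. Values per library are CPM of the TMM-scaled library, that is counts per M counts, given as mean ± SD over 4 libraries. Log2 fold changes are OxPAPC over vehicle, with the SE taken as the absolute log2 fold change divided by the square root of F. The biological coefficient of variation was 5.79%. On simulated data for this comparison, made for the same 13206 genes from the libraries' means and sizes, edgeR recovered 36% of genes changed 1.2-fold, 70% at 1.5-fold, 84% at 2-fold and 98% at 4-fold, with the right sign in each, and 12 of its 170 calls were false. Only 50 genes were changed there at each fold, besides a raised list, against 4533 changed genes in the data. The adjustment of p-values depends on that number, so these rates need not hold for the data.

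A set of 38 gene lists was fixed before the data were examined. It covered NADPH oxidase subunits, NRF2 targets, other antioxidant enzymes, glycolysis and glucose uptake, the pentose phosphate pathway, pyruvate dehydrogenase and the TCA cycle, oxidative phosphorylation encoded in the nucleus and in mitochondria, and fatty acid oxidation. It further covered lipid, stress, inflammatory, growth, muscle and matrix programs, receptors proposed to sense oxidized phospholipids, ribosomal proteins and markers of 7 cell types. The 32 lists with at least 5 tested members were tested with camera in limma 3.58.1 at its preset correlation of 0.01, adjusted over those 32 lists, beside camera with an estimated correlation and fry. On simulated data camera called a list whose members had been raised and 0 of 30 null lists. Genes were drawn there independently of each other, so this does not show how often camera calls lists of correlated genes falsely. Of the 696 symbols listed, 5 matched no gene (Trim16l, Hspa1a, Rigi, Mt1a and Mt2). Total counts, the mitochondrially encoded share of counts and the share of the 20 largest genes were compared by an exact two-sided permutation test over 70 assignments, adjusted over these 3.

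The genes named were fixed by a rule before the data were examined. Its first part took the 8 largest rises and the 8 largest falls among changed protein-coding genes with a mean of at least 1 CPM and no overlap between the 4 and 4 libraries. Its second part took from each list the members with the smallest p, 3 from 7 lists (NADPH oxidase subunits, NRF2 targets, glycolysis, pentose phosphate, pyruvate dehydrogenase and TCA cycle, ATF4, NF-kappaB) and 2 from every other list. Its last part took Nox1, Nox4, Cybb, Cyba, Hmox1, Nqo1, Slc2a1, Hk2, Pfkfb3, Ldha and Pdk4 whatever their result. Some further genes chosen by this rule are not reported here by name, but stay in every test and count. Any other gene named was chosen after its values were seen, mostly because it moved against its list or belonged to a count of 5 or fewer.

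The alternatives fixed before the data were examined were RLE factors, upper-quartile factors, library totals, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in 4 libraries, protein-coding genes only, and each library left out in turn. They further held a block of consecutive title numbers, an adjusted p under 0.01, glmTreat against a 1.2-fold change, and limma on the authors' FPKM with pseudocounts of 1 and 0.1, a minimum mean of 0.5 FPKM or no filter. For lists they held fry, the estimated correlation and members of 1 list only. A fit without vehicle 15 and OxPAPC 23 and a fit with a long-transcript covariate were added after seeing the data. No deposited library was left out of the comparison.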

Results

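Messenger RNA was counted per gene in 8 samples of H9c2 rat cardiac myoblasts, 4 after 6 h with 100 µg/ml OxPAPC and 4 with vehicle. Total counts were 18.3 ± 2.27 M (SD, n = 4) per vehicle library and 17.5 ± 2.22 M (SD, n = 4) per OxPAPC library, and 17838 to 18556 genes had a count in a library. The first principal component of log2 CPM held 45.8% of the variance and separated the groups, and the second held 14.4%. Collagen I alpha 1 (Col1a1) was the largest gene in each library, with 3.85 to 4.30% of the counts. Values after ± beside a log2 fold change are SE, and adjusted p-values of single genes come from edgeR.

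The comparison addressed how cardiac cells respond to oxidized phosphatidylcholines, with NOX1, oxidative stress and glucose metabolism as the study's stated interests. OxPAPC changed 4533 of 13206 tested genes (34.3%), of which 2369 rose and 2164 fell, while 5606 genes had an unadjusted p under 0.05. Most changes were small, since 84.3% of the changed genes moved less than 1.5-fold and the median absolute log2 fold change among them was 0.28. At least 2-fold, 135 genes rose and 68 fell, and at least 4-fold, 27 rose and 4 fell. The changed genes included 4398 of 12248 protein-coding genes and 86 of 614 long noncoding RNAs. The split of rises and falls depended on the scaling: with upper-quartile factors 1829 genes rose and 2723 fell, 40.2% against 52.3% rises among the changed genes with TMM, although the median log2 fold change of all genes moved only from 0.0022 to −0.035.

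**Figure D1:**
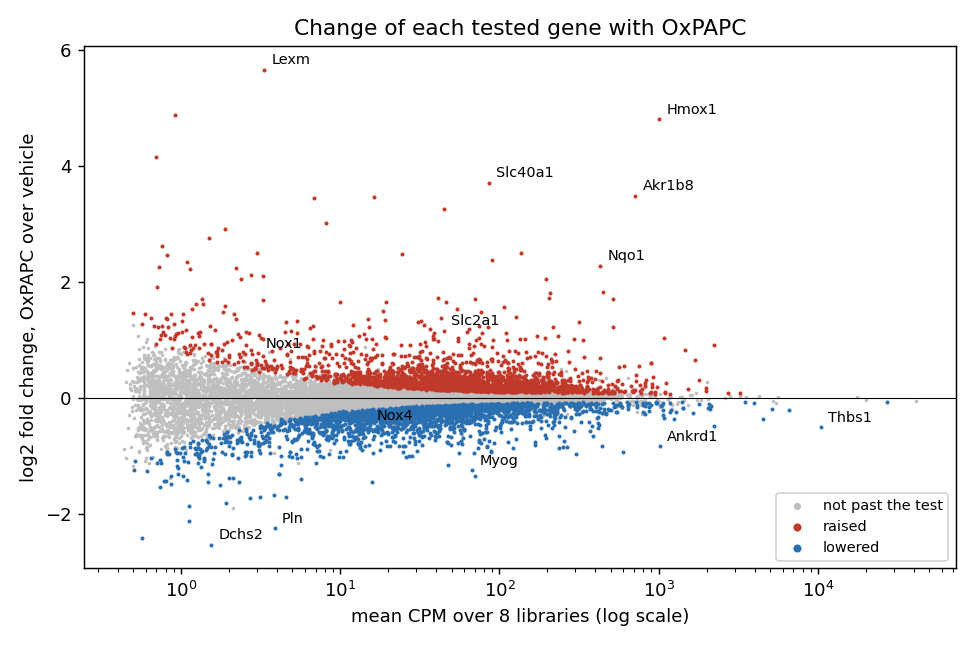
Log2 fold change of OxPAPC over vehicle (vertical axis) against the mean CPM of 8 libraries (horizontal axis, log scale) for the 13206 tested genes, with each point 1 gene. The 2369 raised genes are red, the 2164 lowered genes blue and the others grey; Hmox1 combined a large rise, 4.81, with high abundance.

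Among the largest rises were genes of heme and iron metabolism and of aldehyde reduction. Heme oxygenase 1 (Hmox1, gene 24451, chromosome 19, 13466287 to 13474082), which degrades heme, rose from 69.4 ± 3.83 to 1943 ± 54.2 CPM (SD, n = 4), a log2 fold change of 4.81 ± 0.04 (edgeR adjusted p = 2.34e-25). The iron exporter ferroportin (Slc40a1, gene 170840, chromosome 9, 48033526 to 48053876) rose from 12.2 ± 0.474 to 159.9 ± 9.45 CPM (3.71 ± 0.05, edgeR adjusted p = 2.37e-23). The aldo-keto reductases Akr1b8 and Akr1b10, which reduce reactive aldehydes, rose by 3.49 ± 0.04 and 3.26 ± 0.31. Their counts are uncertain to the extent that reads of these similar genes were shared, and Akr1b10 also overlaps Akr1b7 on the same strand. The largest rise among the named genes was that of Lexm (5.66 ± 0.31, from 0.115 to 6.56 CPM, with 0 to 5 counts per vehicle library; 6.28 without vehicle 8 and 1.99 with log2(FPKM + 1)), and further ones were those of the vasodilator peptide adrenomedullin (Adm, 3.47 ± 0.13), the stress-induced growth inhibitor Osgin1 (3.44 ± 0.16) and the AMP deaminase Ampd3 (3.01 ± 0.15).

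The largest falls were in genes of low abundance. They were those of the cadherin Dchs2 (−2.54 ± 0.34, from 2.63 to 0.475 CPM, −3.14 without OxPAPC 2 and −0.21 with log2(FPKM + 1) and no filter), phospholamban (Pln, −2.25 ± 0.21), the regulator of the calcium pump of the sarcoplasmic reticulum, and Bicdl2 (−1.88 ± 0.32). The Notch ligand Dll1 (−1.81 ± 0.26), the inflammasome sensor Nlrp3 (−1.73 ± 0.21), the exchange factor Arhgef26 (−1.71 ± 0.15), the growth factor Fgf18 (−1.71 ± 0.20) and the transcription factor Pou2f2 (−1.67 ± 0.17) followed. Pln lies within the span of Cep85l on the opposite strand and Dll1 overlaps Fam120b, so part of their counts is uncertain, although neither neighbour passed the test (−0.16, adjusted p = 0.181, and 0.07, adjusted p = 0.323).

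Of the tested catalytic NADPH oxidase subunits, which make superoxide or hydrogen peroxide, Nox1 and Duox2 rose, Nox4 fell and Duox1 did not pass. Duox1 was the most abundant of them, with 77.0 ± 2.91 CPM in vehicle and 79.2 ± 2.37 CPM in OxPAPC (SD, n = 4). Its log2 fold change was 0.04 ± 0.04 (edgeR adjusted p = 0.504). Nox1 (gene 114243, chromosome X, 97279058 to 97332291, minus strand) was scarce, with 35 to 84 counts per library, and rose from 2.26 ± 0.218 to 3.87 ± 0.613 CPM (SD, n = 4), a log2 fold change of 0.77 ± 0.18 (edgeR adjusted p = 0.00174). All 4 OxPAPC libraries lay above all 4 vehicle libraries, and with log2(FPKM + 1) the change was 0.37. Nox1 shares 419 bases with Cstf2 on the opposite strand, a gene with 12906 counts that also rose (0.34 ± 0.04, edgeR adjusted p = 7.33e-07). Nox1 counts were 2.86% of those of Cstf2 in vehicle and 3.81% in OxPAPC, and their log2 ratio did not differ past the threshold (−5.14 ± 0.14 against −4.72 ± 0.23, SD, n = 4, exact two-sided permutation p = 0.0571). Nox4, more abundant than Nox1 here, fell from 17.8 ± 1.17 to 12.8 ± 0.778 CPM (SD, n = 4; −0.47 ± 0.08, edgeR adjusted p = 8.05e-05). Duox2, which overlaps Duoxa2, rose by 0.27 ± 0.08 (edgeR adjusted p = 0.0159). It did not pass without OxPAPC 9 (adjusted p = 0.0901) or with limma on the FPKM values (0.136 to 0.2), over a range of 0.00453 to 0.2. Cyba, the p22phox partner of NOX enzymes, had 76.8 ± 1.27 and 74.3 ± 1.45 CPM (SD, n = 4; −0.05 ± 0.04, edgeR adjusted p = 0.368). No count of Cybb, Nox3, Ncf4, Noxa1 or Rac2 was found in the 8 libraries, which for Cybb allows up to 0.0409 CPM in vehicle and 0.0428 CPM in OxPAPC (3 counts over a group). Ncf1 and Noxo1 had 8 and 1 counts over all libraries. Among the 7 tested members of the list 2 rose, 1 fell and 4 did not pass, as also adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.849).

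Targets of NRF2, the transcription factor of the response to oxidants and electrophiles, rose together. All 28 tested members rose, also adjusted over the list alone, 18 of them at least 2-fold, with a median log2 fold change of 1.05 (camera adjusted p = 9.54e-220, and 2.98e-05 with an estimated correlation). NAD(P)H quinone dehydrogenase 1 (Nqo1, gene 24314, chromosome 19, 35295633 to 35310528) rose from 146.4 ± 3.62 to 712.1 ± 13.6 CPM (SD, n = 4; 2.28 ± 0.03, edgeR adjusted p = 3.87e-24). The ferritin genes of this list are among 12 tested genes with a ferritin domain, and shared reads between them were not excluded. Among other antioxidant enzymes, catalase (Cat, 2.06 ± 0.04) and peroxiredoxin 6 (Prdx6, 0.80 ± 0.04) led, and 7 of 21 rose, 1 fell (Msrb1, −0.14 ± 0.05) and 13 did not pass (7, 4 and 10 adjusted over the list alone). That list was called (camera adjusted p = 0.000661), but not with limma-voom (adjusted p = 0.1) or with the FPKM values (0.181 to 0.268), over a range of 2.45e-06 to 0.268. Genes of iron handling and ferroptosis included Hmox1 and Slc40a1, and 11 of 18 rose, 1 fell (Aifm2, −0.15 ± 0.05) and 6 did not pass (11, 2 and 5 adjusted over the list alone; camera adjusted p = 9.13e-37).

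Transcripts of glucose uptake and of most steps of glycolysis rose modestly. The glucose transporter GLUT1 (Slc2a1, gene 24778, chromosome 5, 132717196 to 132745416) rose from 27.7 ± 1.37 to 61.6 ± 2.81 CPM (SD, n = 4; 1.15 ± 0.05, edgeR adjusted p = 7.59e-14). The hexokinases Hk1 (0.40 ± 0.03) and Hk2 (0.44 ± 0.05) and aldolase A (Aldoa, 0.26 ± 0.02) rose as well. The muscle and fat glucose transporter GLUT4 (Slc2a4, −0.40 ± 0.08) and muscle phosphofructokinase (Pfkm, −0.18 ± 0.05) fell. Of 22 tested members 15 rose, 2 fell and 5 did not pass (17, 3 and 2 adjusted over the list alone; camera adjusted p = 2.46e-05). Lactate dehydrogenase A (Ldha) had 756.5 ± 11.8 and 787 ± 16.4 CPM (SD, n = 4; 0.06 ± 0.03, edgeR adjusted p = 0.0879), and the log2 fold change of the glycolytic regulator Pfkfb3 was 0.14 ± 0.11 (edgeR adjusted p = 0.355), neither past the threshold.

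The pentose phosphate pathway, which makes NADPH and ribose, rose at both its oxidative and nonoxidative steps. Pgd (1.02 ± 0.03), Tkt (1.06 ± 0.03) and Taldo1 (1.04 ± 0.03) about doubled. Of 10 members 6 rose, 1 fell (the ribose-phosphate kinase Prps2, −0.26 ± 0.07) and 3 did not pass, as also adjusted over the list alone (camera adjusted p = 1.43e-11). These 3 enzymes are also NRF2 targets in the fixed lists, and with members of 1 list only the pathway was not called (adjusted p = 0.663, range 1.09e-16 to 0.663).

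**Figure D2:**
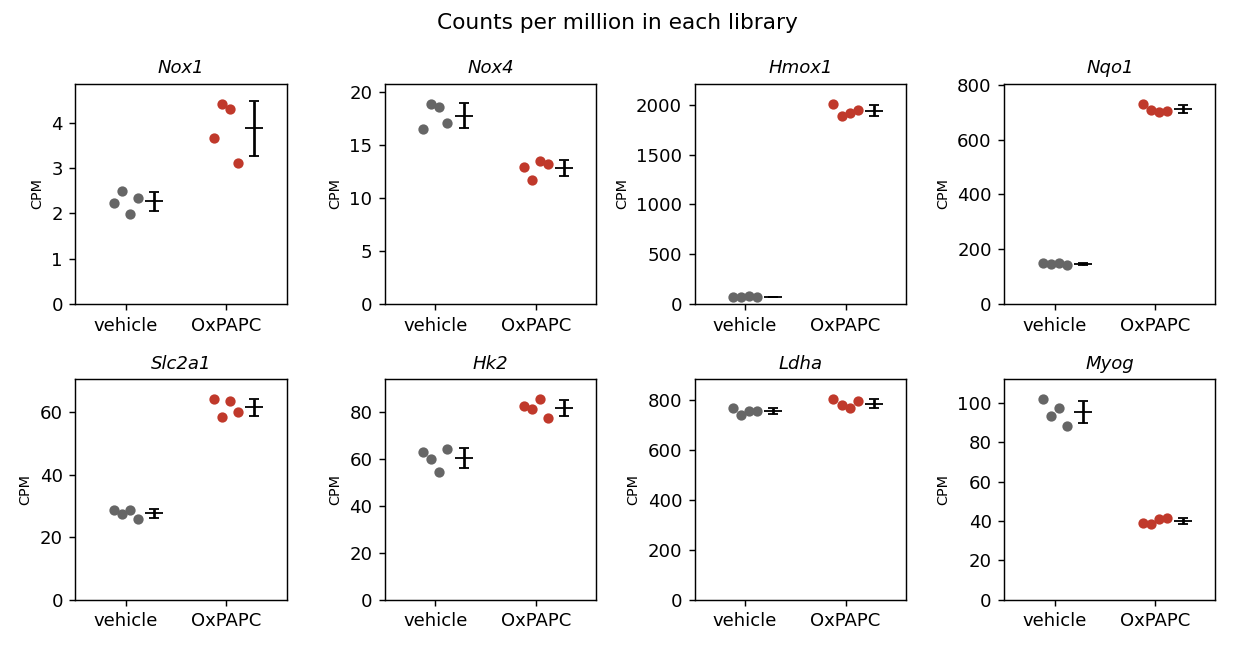
CPM (vertical axes, starting at 0) of 8 genes in the 4 vehicle (grey) and 4 OxPAPC (red) libraries, with 1 point per library and mean ± SD in black. Nox1, Hmox1, Nqo1, Slc2a1 and Hk2 were higher in all 4 OxPAPC libraries, Nox4 and Myog were lower in all 4, and the groups overlapped for Ldha.

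Mitochondrial energy metabolism showed few and small changes, with more falls than rises past the test. In pyruvate dehydrogenase and the TCA cycle, 2 of 30 members rose, 5 fell and 23 did not pass, as also adjusted over the list alone, and the list was not called (camera adjusted p = 0.266). Pyruvate carboxylase (Pc), which feeds pyruvate into the cycle, rose by 0.59 ± 0.06, but overlaps Lrfn4 on the opposite strand, which also rose (0.26, edgeR adjusted p = 0.000857). The phosphatase Pdp1 (0.31 ± 0.09) also rose, and isocitrate dehydrogenase 2 (Idh2, −0.30 ± 0.03), the pyruvate dehydrogenase subunit Pdha1 (−0.21 ± 0.04), Fh, Pdk1 and Suclg2 fell. Pdk4, a kinase that inhibits pyruvate dehydrogenase, was too scarce to test, with 8 counts over the vehicle and 5 over the OxPAPC libraries. Of 52 oxidative phosphorylation genes of the nucleus 2 rose, 8 fell and 42 did not pass (2, 6 and 44 adjusted over the list alone). That list was not called (camera adjusted p = 0.295), with Atp5pd at 0.20 ± 0.05 and Atp5f1a at −0.14 ± 0.03. Over the alternatives for lists, the adjusted p ran from 0.000721 to 0.411 for pyruvate dehydrogenase and the TCA cycle. For nuclear oxidative phosphorylation it ran from 0.000721 to 0.795, so the call of both lists depended on the alternative.

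Of the 13 mitochondrially encoded transcripts 1 fell, ATP6 (−0.24 ± 0.07, edgeR adjusted p = 0.028), and 12 did not pass, among them ND1 (−0.28 ± 0.09, edgeR adjusted p = 0.0517). Adjusted over the list alone none passed, and the list was not called (camera adjusted p = 0.105), though without vehicle 15 it was (0.0329, range 0.0034 to 0.606). ATP6 did not pass without OxPAPC 2 (adjusted p = 0.0591) or without OxPAPC 9 (0.0761), over a range of 4.49e-05 to 0.0761. Nor did it pass without vehicle 15 and OxPAPC 23 together (0.0622) or with the long-transcript covariate (0.0572). ND1 passed without vehicle 8 (0.000409) and without vehicle 15 (0.0483), over a range of 9.6e-05 to 0.122. It also passed with RLE factors (edgeR adjusted p = 0.049), upper-quartile factors (0.0299), library totals (0.0334) and DESeq2 (9.6e-05). The filter of at least 1 CPM in 4 libraries (0.0491), the replicate block (0.0493) and limma on the FPKM values (0.0208 to 0.0313) called it too, while the other alternatives did not. The mitochondrially encoded share of counts was 1.38 ± 0.139% in vehicle and 1.25 ± 0.0571% in OxPAPC (SD, n = 4; exact two-sided permutation p = 0.0571, adjusted p = 0.0857). Without vehicle 15 that difference was −0.169 percentage points and passed (exact permutation adjusted p = 0.0429). Without vehicle 8, the library with the highest share, it was only −0.0672 percentage points and did not pass (exact permutation adjusted p = 0.171).

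Lipid genes split by pathway. PPAR-responsive genes of lipid handling rose in 5 of 12, including the carnitine palmitoyltransferase Cpt1a (1.21 ± 0.04), which admits fatty acids to mitochondria, the thioesterase Acot2 (1.25 ± 0.08), Plin2, Angptl4 and Slc25a20. The other 7 did not pass, as also adjusted over the list alone (camera adjusted p = 9.58e-05). Fatty acid oxidation had 3 rises, 3 falls and 15 members that did not pass, as also adjusted over the list alone. Cpt1a, Hadhb and Slc25a20 rose, Hadh (−0.46 ± 0.10), Echs1 and Etfb fell, and the list was not called (camera adjusted p = 0.621). Its median was −0.05, while its mean, 0.015, and the direction of camera were upward. Cholesterol synthesis genes fell in 13 of 24, with no rise and 11 not past the test (1 raised, 15 lowered and 8 not past adjusted over the list alone). Hmgcs1 (−0.48 ± 0.04) and Dhcr7 (−0.83 ± 0.07) had the smallest p in this list. The list was called (camera adjusted p = 8.58e-06), but not with an estimated correlation (adjusted p = 0.0677, range 1.75e-09 to 0.0677). Among 12 genes of LXR and fatty acid synthesis, 2 rose (Srebf1, Nr1h2), 4 fell (Elovl6, −0.77 ± 0.07, Fads1, −0.32 ± 0.04, Fasn and Acaca) and 6 did not pass, as also adjusted over the list alone. It was not called (camera adjusted p = 0.164), with a median of 0.07 against a mean of −0.12 and a downward camera direction, and it was called without vehicle 15 (0.0221, range 0.0128 to 0.476).

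The lists of cytosolic heat shock proteins and of endoplasmic reticulum chaperones moved in opposite directions. Both held some other genes, as Hspd1 and Hspe1 are mitochondrial and Atf6 and Xbp1 are transcription factors. Of 17 genes in the heat shock list 16 rose, none fell and 1 (Hspa4l) did not pass, as also adjusted over the list alone, with a median of 0.55 (camera adjusted p = 1.83e-21). Hspa8 rose by 0.83 ± 0.02, with copies that may share its reads, and Hsp90ab1 by 0.65 ± 0.02. Genes of the endoplasmic reticulum list fell in 13 of 20, including BiP (Hspa5, −0.35 ± 0.03) and Creld2 (−0.56 ± 0.06), while 2 rose (Dnajb9, Atf6) and 5 did not pass (4 raised, 13 lowered and 3 not past adjusted over the list alone). That list was called (camera adjusted p = 0.00294), but not with an estimated correlation (adjusted p = 0.234, range 8.34e-07 to 0.234). ATF4 and integrated stress response genes rose in 22 of 24. Slc3a2 (0.99 ± 0.03), the heavy chain of amino acid transporters, Cebpb (0.78 ± 0.04) and the phosphatase subunit Ppp1r15a (0.61 ± 0.05) had the smallest p. Vldlr fell (−0.33 ± 0.03) and Gars did not pass, as also adjusted over the list alone (camera adjusted p = 3.39e-15).

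Several further stress lists were raised. The aryl hydrocarbon receptor and aldehyde metabolism list rose in 7 of 12, with Nqo1 and Akr1b1 (1.71 ± 0.03), fell in 2 (Cyp1b1, Aldh7a1) and did not pass in 3, as also adjusted over the list alone (camera adjusted p = 5.99e-19). Besides the receptor gene Ahr itself (1.71 ± 0.05), its largest rises were those of the aldo-keto reductases and of Nqo1, which is also an NRF2 target. Of the classical targets of the receptor, Cyp1b1 fell by 0.16 on the log2 scale, Tiparp rose by 0.36 and Ahrr did not pass. Immediate early genes rose in 12 of 22, fell in 3 (Egr1, Klf4, Fos) and did not pass in 7 (12, 4 and 6 adjusted over the list alone), and the list was called (camera adjusted p = 2.8e-07). Fosl1 (1.65 ± 0.05) and Ier3 (1.00 ± 0.04) had the smallest p among them. The hypoxia list had Adm and Slc2a1 among 7 rises of 15, 2 falls (Pdk1, Ca9) and 6 not past, as also adjusted over the list alone (camera adjusted p = 5.52e-05). Targets of p53 rose in 9 of 15, with Gadd45a (0.63 ± 0.04) and Phlda3 (0.42 ± 0.04), fell in 2 (Plk2, Btg2) and did not pass in 4 (9, 3 and 3 adjusted over the list alone; camera adjusted p = 0.000491). Autophagy and lysosome genes rose in 16 of 25, with the cargo receptor Sqstm1 (1.21 ± 0.03) and Gabarapl1 (1.12 ± 0.05), fell in 2 (Becn1, Wipi1) and did not pass in 7, as also adjusted over the list alone (camera adjusted p = 7.9e-05). Of 4 tested metallothionein and zinc genes, too few for camera, Slc39a10 (0.47 ± 0.05) and Mtf1 rose, Slc30a1 (−0.39 ± 0.07) fell and Mt1 did not pass, as also adjusted over the list alone.

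Inflammatory and death programs were not called as lists. Of 18 NF-kappaB and inflammatory mediators 7 rose, none fell and 11 did not pass, as also adjusted over the list alone (camera adjusted p = 0.0802). Csf1 (0.30 ± 0.03), Relb (0.70 ± 0.13) and the monocyte chemokine Ccl2 (2.26 ± 0.44, with 1 to 29 counts per library) had the smallest p of them. The list was called without vehicle 1 (0.049) and without OxPAPC 16 (0.0429), over a range of 0.00339 to 0.387. Among 13 interferon response genes 2 fell, including Stat2 (−0.26 ± 0.05), Irf9 rose and 10 did not pass, as also adjusted over the list alone (camera adjusted p = 0.0944). Apoptosis regulators rose in 5 of 21 (Bax, 0.33 ± 0.04, Mcl1, 0.23 ± 0.04, Bid, Bmf and Casp8), fell in 1 and did not pass in 15, as also adjusted over the list alone (camera adjusted p = 0.363). Of 6 receptors proposed to sense oxidized phospholipids, the scavenger receptor Olr1 (−1.21 ± 0.32, from 1.33 to 0.578 CPM) and the platelet-activating factor receptor Ptafr (−0.35 ± 0.10) fell and 4 did not pass, as also adjusted over the list alone (camera adjusted p = 0.229).

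DNA replication and cell cycle genes fell together. Of 30 members 26 fell, none rose and 4 (Ccnb2, Pcna, Mki67 and Aurka) did not pass (28 lowered and 2 not past adjusted over the list alone), with a median of −0.51 (camera adjusted p = 1.87e-28). Over the alternatives for lists, its adjusted p ran from 3.21e-47 to 0.00336. The replicative helicase subunits Mcm2 (from 117.2 ± 1.05 to 68.2 ± 2.15 CPM, SD, n = 4; −0.78 ± 0.04, edgeR adjusted p = 1.6e-13) and Mcm5 (−0.93 ± 0.05, edgeR adjusted p = 1.82e-13) had the smallest p.

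Muscle and matrix lists had more falls than rises. Myogenin (Myog), a driver of myoblast differentiation, fell from 95.1 ± 5.67 to 40 ± 1.46 CPM (SD, n = 4; −1.25 ± 0.05, edgeR adjusted p = 3.08e-15), and Mef2c fell by 0.44 on the log2 scale. Of 23 myogenic genes 9 fell, 2 rose (Mef2d, Myod1) and 12 did not pass, as also adjusted over the list alone. The list was called (camera adjusted p = 0.00317), but not with an estimated correlation (adjusted p = 0.136, range 0.000104 to 0.136). Smooth muscle markers, abundant in the vehicle libraries (Acta2, 5094 CPM), fell in 7 of 8, with Lmod1 (−0.70 ± 0.03) and myosin light chain kinase (Mylk, −0.77 ± 0.04), and Myh11 did not pass (8 lowered adjusted over the list alone; camera adjusted p = 4.62e-09). Cardiac stress genes had 2 rises (Rcan1, 0.65 ± 0.04, and Csrp3), 3 falls (Ankrd1, −0.84 ± 0.03, Mef2c and Acta1) and 5 members not past the test (3, 4 and 3 adjusted over the list alone). That list was not called (camera adjusted p = 0.311), with a median of 0.08 and a mean of 0.05 against a downward camera direction. Matrix and TGF-beta target genes fell in 11 of 25, including Tgfb3 (−0.94 ± 0.03) and Ccn2 (−0.49 ± 0.02), rose in 2 (Timp1, Mmp2) and did not pass in 12 (2 raised, 13 lowered and 10 not past adjusted over the list alone). It was called (camera adjusted p = 0.00203), but not with an estimated correlation (adjusted p = 0.373, range 2.34e-05 to 0.373).

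**Figure D3:**
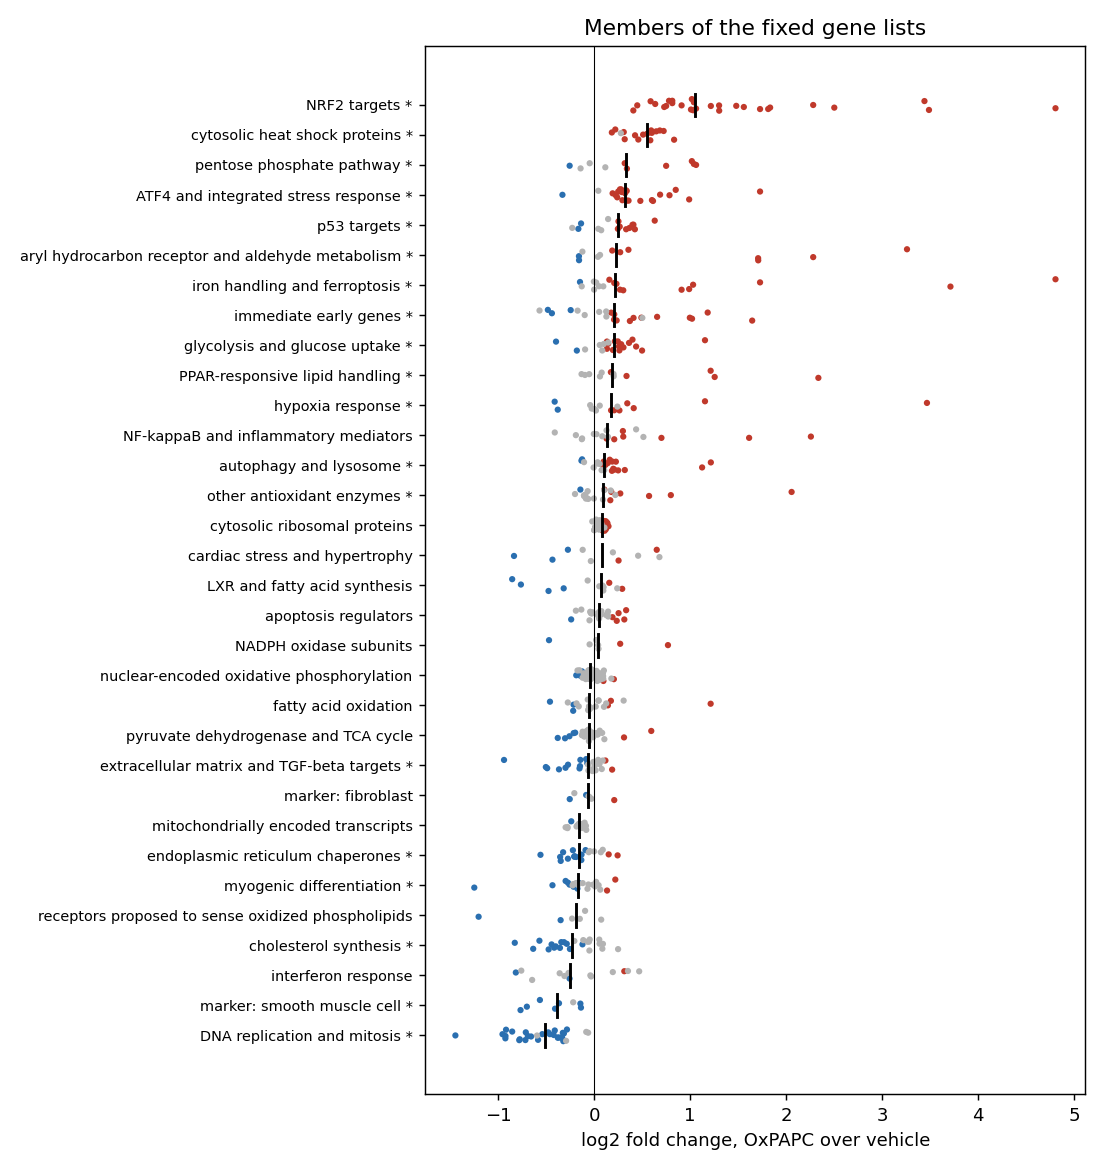
Log2 fold change of OxPAPC over vehicle (horizontal axis) for each tested member (point) of the 32 lists tested by camera, ordered by their median (black bar), with raised members red, lowered members blue and members not past the test grey. An asterisk marks the 19 lists called; NRF2 targets had the highest median, 1.05, and DNA replication and mitosis the lowest, −0.51.

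In the fibroblast list Ddr2 rose (0.21 ± 0.04), Col15a1 (−0.26 ± 0.05) and Thy1 fell and 4 of 7 did not pass, as also adjusted over the list alone (camera adjusted p = 0.473). Of 3 tested mature cardiomyocyte markers Pln and Tnnt2 (−0.18 ± 0.04) fell and Actn2 did not pass, as also adjusted over the list alone. None of the 3 tested macrophage markers passed, with Cd14 at −0.15 ± 0.07 (edgeR adjusted p = 0.0862) and Csf1r at 0.65 ± 0.34 (0.151). Nor did the only tested markers of endothelial cells (Vwf, 0.26 ± 0.55), epithelial cells (Krt8, 0.06 ± 0.06) and adipocytes (Lipe, −0.10 ± 0.29), and adjusted over the list alone these counts were the same. Cytosolic ribosomal proteins, many of which have pseudogene copies, rose in 13 of 32 and 19 did not pass (15 raised and 17 not past adjusted over the list alone; camera adjusted p = 0.105).

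Over all lists camera called 19 of 32, 13 upward and 6 downward, of which 15 were called with an estimated correlation, all but cholesterol synthesis, endoplasmic reticulum chaperones, myogenic differentiation and matrix genes. The very small p-values of several other lists depended on the setting, though each stayed under the threshold. Over the alternatives the adjusted p reached 0.00273 for cytosolic heat shock proteins, 0.0136 for ATF4 and the integrated stress response and 0.0139 for smooth muscle markers. Total counts did not differ past the threshold (exact two-sided permutation p = 0.686, adjusted p = 0.686), and the order of the group means was reversed without vehicle 8 (a difference of 0.342 M counts, exact permutation adjusted p = 0.743). The 20 largest genes held 18.4 ± 0.361% of counts in vehicle and 17.3 ± 0.285% in OxPAPC (SD, n = 4; exact two-sided permutation p = 0.0286, the smallest that 70 assignments can give, adjusted p = 0.0857). Without vehicle 15 the adjusted p of that share was 0.0429, because the mitochondrially encoded share then reached the smallest p as well, which eased the adjustment.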

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

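Of the tests given here, those of the splits of the libraries, of the long transcripts, of the scaling, of RNA integrity and of replication against mitosis, of counting noise, NADPH oxidase paralogs and a constant Cstf2 share were chosen after the result was seen.

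In 11 of 194 groups of 4 libraries that were checked, the highest or the lowest library lay far from the nearest other one (Dixon's gap over range, limit for 1 in 20). Chance gives about 1 in 20, or 9.7 here, and 10 of the 11 are given. The vehicle 8 library had the most counts of its group, 21.73 M, the highest mitochondrially encoded share, 1.59%, and the most ATP6, 1425 CPM. In vehicle 15 the 20 largest genes held 17.87% of counts, the least of its group. Vehicle 22 was lowest in Lipe (0.759 CPM). OxPAPC 2 was lowest in Elovl6 (14.9 CPM) and highest in Ppp1r15a (81.5 CPM), OxPAPC 9 lowest in Ptafr (8.89 CPM), OxPAPC 16 highest in Pdha1 (125.6 CPM) and OxPAPC 23 lowest in Ankrd1 (697.6 CPM).

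The 8 libraries can be split into 4 and 4 in 35 ways, and for each of the 4 gene counts only 1 split, the real one, gave a count as large. That is the smallest share that 35 splits can give. Every other split mixed OxPAPC and vehicle libraries on each side, so the treatment itself widened the spread there. Those splits therefore do not show what chance alone would give. The real split gave 4533 changed genes, 2369 raised and 2164 lowered, against at most 1 in any of the other splits, and 203 genes changed at least 2-fold against 0. For the lists called, too, only the real split gave as many, but by a margin of 1 list (19 against 18). Every split with over 3 lists called had at least 3 libraries of one group on the same side, so it still carried part of the treatment.

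Transcripts of at least 10 kb differed between libraries of the same group, as vehicle 15 and OxPAPC 23 had the lowest mean log2 CPM over 904 such genes (4.62 and 4.61, with group means of 4.71 ± 0.068 and 4.70 ± 0.058, SD, n = 4). Depth argues against itself as the cause, since the score and total counts were hardly related over 8 libraries (Spearman 0.119, permutation p = 0.793, Pearson 0.031, p = 0.946, and 0.004 without the 2 libraries farthest from the median total). The treatment cannot explain a low library in each group, and the scores did not differ past the threshold between groups (exact two-sided permutation p = 0.743). Lower RNA integrity in these 2 libraries may be the cause, as the median deviation fell in 7 of 8 steps from shorter to longer transcripts, but it cannot be told apart from other length biases without coverage along transcripts. Without both libraries 4504 genes were changed, and with the score as a covariate 5161.

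The median log2 fold change of the DNA replication and mitosis genes was −0.51, and it was −0.514 to −0.548 with RLE, upper-quartile and total-count scaling, which argues against a choice among these scalings as its cause, while a change in total RNA per cell was not measured here. Without the 2 libraries with the lowest long-transcript scores it was −0.544 (quartiles of −0.78 and −0.365), so the fall did not rest on those 2 libraries. As they lay in different groups, leaving both out says little about RNA integrity as a cause. Genes raised at least 2-fold grew from 0.433% to 1.42% of counts, which would lower every other gene by only −0.0143 on the log2 scale. The 16 replication genes fell more than the 14 mitotic ones (medians of −0.75 and −0.34, exact two-sided permutation p = 0.0286, the smallest possible). Whether fewer cells were in S phase was not tested here and stays open, and DNA content or EdU labelling would decide it.

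The rise of Nox1 was larger than counting noise, as the ratio of pooled CPM was 1.70 with a 95% exact interval of 1.39 to 2.07. Reads from Nox3, Nox4 and Cybb do not account for it, because Nox3 and Cybb had no counts and the summed level of the 3 changed by −5.06 CPM while Nox1 gained 1.58 CPM. Of 3 tested genes within 100 kb, 1 rose by more than that gain, Cstf2, whose span overlaps that of Nox1. A constant share of Cstf2 reads counted as Nox1 cannot be told apart from a rise of Nox1 itself, since the ratio of both did not differ past the threshold (exact two-sided permutation p = 0.0571), although 3 of 4 OxPAPC libraries lay above every vehicle library. The read positions and strands that would settle it were not analysed here, so regulation of Nox1 by OxPAPC stays an open explanation beside it.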

How the results depend on the processing

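Among the alternatives here, only the fit without vehicle 15 and OxPAPC 23 and the long-transcript covariate were chosen after seeing the data. The count of changed genes was 3134 to 5161 over the alternatives that tested for any change, raised 1488 to 2707 and lowered 1450 to 2723, while 1016 passed a test against a fold of 1.2 (glmTreat). Changed, raised and lowered genes numbered 3919 to 4397, 2060 to 2336 and 1853 to 2082 with each library left out in turn. The raised count was moved beyond 1.5 times by FPKM without a filter (1488). Against 203, the count of genes changed at least 2-fold was 307 without a filter. It was 172 with an adjusted p under 0.01, 59 with log2(FPKM + 1), with or without a filter, and 116 with log2(FPKM + 0.1), and 210 to 229 with a library left out. Between 15 and 28 lists were called, and 19 to 21 with a library left out.

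With each library left out, the group difference in the mitochondrially encoded share of counts was −0.169 (without vehicle 15) to −0.0672 percentage points (without vehicle 8). In the share of counts in the 20 largest genes it was −1.33 (without vehicle 15) to −1.03 (without OxPAPC 23). Both passed only without vehicle 15 (exact permutation adjusted p = 0.0429). The share of the 20 largest genes was already at the smallest exact permutation p, 0.0286, with all libraries, and adjusted there to 0.0857. Its pass without vehicle 15 followed from the adjustment, as the mitochondrially encoded share then reached the smallest p too. In total counts per library the difference was −1.54 M (without OxPAPC 23) to 0.342 M (without vehicle 8, reversed). The cause of the other shifts was not tested.

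Of 2007 values of 92 named genes, 1980 kept direction and side of the threshold, 8 lost a call, 16 gained one and 3 reversed. With log2(FPKM + 1) the folds of 10 named genes, and without a filter of 14, came nearer to 1 by over 1.5 times. The losses were those of Duox2 and ATP6, the gains those of ND1, Cd14 and Cyba. Vwf, at 1 to 19 counts per library and never past the test, ranged from −0.159 to 0.624 with a library left out, with reversals without OxPAPC 23 (−0.159) and without vehicle 15 (−0.09), and was −0.514 without vehicle 15 and OxPAPC 23. Of 800 list values, 749 were the same, 9 lost a call, 37 gained one and 5 reversed. The reversals were those of fatty acid oxidation, never past the threshold in that direction, with adjusted p = 0.895 (limma-voom), 0.694, 0.686 and 0.557 (FPKM with pseudocounts of 1 and 0.1 and without a filter) and 0.47 (members of 1 list only). The cause was not tested.

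Whether the title numbers pair the samples stays open. Residuals of consecutive numbers correlated at 0.211, −0.001, 0.03 and 0.014. Only vehicle 1 correlated best with the OxPAPC library of the next number. These few correlations show little sign of pairing but cannot rule it out. With a replicate block of these numbers 4664 genes were changed, against 4533 without it, and 19 lists were called either way. Depth limits the scarce genes, as Nox1 rests on 35 to 84 counts per library and Cybb and Pdk4 could not be tested.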

Other observations

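The tests of protein domain families and of aryl hydrocarbon receptor targets below were chosen after the result was seen; the lists of SRF and YAP targets were written before their values were looked at, but after the fall of smooth muscle genes was known.

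Some protein families moved as well, several of them with members that are also in the fixed lists, such as Fth1, Hspd1, Kdm3a, Thbs1 and Ccn2. Families were taken from Pfam domains in the gene descriptions of the deposited table and tested by Fisher's exact test, 240 domains in both directions (480 tests, background 9535 genes, genes not independent), and 10 tests passed after Benjamini-Hochberg adjustment. Genes with a proteasome subunit domain, most of them subunits of the core that degrades marked proteins, rose in 11 of 20 (55% against 18.9% of background genes, adjusted p = 0.0264), as Psma1 (0.34 ± 0.03) and Psma5 (0.32 ± 0.05). None fell. The 5 with a mean under 10 CPM, LOC100360846, LOC100361067, LOC688432, Psmb8 and Psmb9, did not pass. Members of the TCP-1 chaperonin family, which includes the chaperonin that folds actin and tubulin, rose in 9 of 16 (adjusted p = 0.0459), as Cct6a (0.25 ± 0.03). Transcription factors with an Ets domain rose in 8 of 12 (adjusted p = 0.0264), with Ets2 (0.76 ± 0.05) and Etv5 (0.51 ± 0.05) highest. Proteins with a JmjC domain, many of them histone demethylases, rose in 9 of 14 (adjusted p = 0.0232), among them Kdm3a (0.41 ± 0.06) and Kdm6b (0.27 ± 0.05). UBA-like proteins rose in 8 of 11 (adjusted p = 0.0185).

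Kinesin motors, several of which work in mitosis, fell in 16 of 29 (adjusted p = 0.000894), as Kif4a (−0.44 ± 0.06) and Kif11 (−0.41 ± 0.06), and so did the cargo motor Kif5b (−0.29 ± 0.03), while Kif21a (0.29), Kif13a (0.26) and Kifc3 (0.17) rose. Genes with a von Willebrand factor C domain fell in 8 of 14 (adjusted p = 0.0442), among them Ccn2, Crim1 (−0.57 ± 0.05) and Thbs1 (−0.51 ± 0.04). Rises were rarer than in the background among KRAB zinc fingers, 11 of 165 (adjusted p = 0.00194), but only 16 of these fell and 122 had a mean under 10 CPM, so calls were scarce in both directions. Among cadherins 0 of 38 rose (adjusted p = 0.0346) and 8 fell, with 23 under 10 CPM, and Dchs2 (−2.54 ± 0.34), Cdh3 (−0.74 ± 0.05) and Celsr2 (−0.61 ± 0.10) fell most of those past the test. Ferritin-like genes rose in 11 of 12 (adjusted p = 5.14e-05), but most are scarce loci beside the abundant Fth1 and Ftl1, and shared reads between them were not excluded, so they do not count as independent genes.

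The fall of smooth muscle genes could reflect lower activity of SRF or of YAP and TEAD, which drive contractile and cytoskeletal genes. Of 15 other SRF targets 9 fell and 1 rose, with a median of −0.09 (camera p = 0.055, n = 15 genes), and of 12 YAP targets 6 fell and 1 rose, with a median of −0.15 (camera p = 0.0258, n = 12 genes). The YAP list met the criterion set beforehand, an unadjusted p under 0.05, and the SRF list narrowly missed it. Over both lists the adjusted p-values were 0.0517 for YAP and 0.055 for SRF, and with an estimated correlation p was 0.262 and 0.319, a requirement added after the values were seen, so neither hypothesis is settled.

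The aryl hydrocarbon receptor gene Ahr rose from 33 to 107.8 CPM (1.71 ± 0.05, edgeR adjusted p = 1.23e-16). If receptor activity had risen with the transcript, its classical targets should have risen. Of 3 tested targets 1 did, Tiparp (0.36 ± 0.06), while Cyp1b1 fell (−0.16 ± 0.03) and Ahrr did not pass (0.04 ± 0.06), and Cyp1a1 was not tested. Nqo1, a target of both this receptor and NRF2, rose (2.28 ± 0.03), and the fixed list that holds these genes was called upward. With so few targets a rise of receptor targets stays open.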
